A study of Mus musculus with 10 samples.

How the data were processed

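The study sequenced RNA of neutrophils and of CCR2+ monocytes, isolated by fluorescence-activated sorting from lungs of immunodeficient NOD/scid mice that carried 1 of 2 breast tumours to end point. Per the labels, HCl-001 (TN1) is the highly metastatic tumour and HCl-002 (TN2) the low metastatic tumour. Each library bears a tag number and is named here by tumour and tag. TN1 holds TN1 tag_191 and TN1 tag_482, TN2 holds TN2 tag_367, TN2 tag_706 and TN2 tag_1341, and each tag occurs once among the neutrophil and once among the monocyte libraries, which makes 10 libraries in 4 groups. The labels do not state that the tags are separate animals, so the p-values measure the spread between samples. RNA was purified on RNeasy Micro columns, amplified by Smart-seq2 (full-length cDNA made from small RNA amounts by PCR, without molecular barcodes) and sequenced on a HiSeq 2500 instrument.

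Per the labels, the authors quantified reads with kallisto 0.42.3 against the GRCm38 mouse transcriptome. Per the file headers, each library's deposited table gives an estimated count, the number of reads assigned to a transcript by expectation maximization. The same deposited tables give TPM, the share of transcripts scaled to a fixed total per library. They also give, per the file headers, an effective length in bases for each transcript. A pair of deposited comparison tables, made by the authors with AltAnalyze, holds for each gene a log2 mean per group. In the genes checked these equalled the mean of log2(TPM + 1) over the group's libraries. The deposited comparison tables further give the authors' log2 fold change, signed fold and p-value, with and without adjustment. The test behind these is not stated in the labels. A fold is given there for 13022 genes in monocytes and 10344 in neutrophils. Of the monocyte genes in the authors' deposited table, 1057 had p under 0.05 and 2 had adjusted p under 0.05. Of the neutrophil genes in the authors' deposited table, 771 and 0 did, with a smallest adjusted p of 0.430.

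Transcripts were summed to genes with GENCODE mouse release 21 (GRCm38 coordinates). Of 85276 transcripts per library, 81839 (96.0%) matched the annotation, giving 29893 genes. The 3437 unmatched transcripts held 1.94% to 3.59% of each library's counts and were left out. Libraries held 7239218 to 11311370 estimated counts, and 8851 to 15211 genes reached 5 counts. The TN1 tag_482 libraries had the fewest genes of their cell type, 8851 in neutrophils and 9732 in monocytes. They also had the highest share of TPM on mitochondrially encoded genes, 3.00% and 19.9%, against 0.283% to 0.813% in the other neutrophil libraries and 4.82% to 5.82% in the other monocyte libraries. Replicates correlated with a Spearman coefficient of 0.777 to 0.926 across the 13384 genes tested. Across genes with at least 20 counts over a pair, differences between replicates exceeded counting noise 54.2-fold to 163-fold (chi-square per degree of freedom). Smart-seq2 reads carry no molecular barcodes, so PCR copies stay in the counts and this ratio does not separate variation between samples from amplification.

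Gene counts were rounded and fitted in a single model of the 4 groups with edgeR 4.0.16 (filterByExpr by group with a total of at least 10 counts, TMM normalization, quasi-likelihood F test, 13384 genes, 6 residual degrees of freedom) in R 4.3.3. The biological coefficient of variation was 0.887. The comparisons were TN2 minus TN1 in neutrophils and in monocytes, the difference of these effects (monocytes minus neutrophils), and monocytes minus neutrophils averaged over the tumours. Benjamini-Hochberg adjustment ran over all genes of a comparison with a threshold of 0.05. Fold changes are log2 with a standard error (SE), derived as the absolute log2 fold change over the square root of the F statistic. Levels are CPM (counts scaled to the TMM library size) as mean ± SD over the libraries of a group. Where a side of a comparison had at most 3 counts in all, a floor of 3 counts over that side gave a bound. Where both sides had at most 3, the fold at the bound was set to no change.

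Before the data were examined, the design, the tests, 24 genes, 16 gene lists and 13 lists of cell type markers were fixed from general knowledge of these cells. The gene lists were interferon gamma response, type I interferon-stimulated, cytosolic DNA sensing, MHC class I and II presentation, cytotoxic effectors, azurophil granule, specific and gelatinase granule, NADPH oxidase and redox, inflammatory cytokines and NF-kB, myeloid suppressor associated, trafficking and adhesion, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, immediate early and heat shock, and mitochondrially encoded genes. The marker lists covered neutrophils, monocytes, alveolar and interstitial macrophages, dendritic cells, natural killer cells, lymphocytes, granulocytes of the eosinophil, basophil and mast cell kind, epithelium, endothelium, stroma, erythroid cells and platelets. Lists with at least 5 measured members were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The estimated correlation and fry were run beside it. Named genes are, for each comparison, those past the threshold without overlap between the sides, by smallest p (12 in each direction for the tumours, 5 for the difference, 8 for the cell types). Where none passed, the 3 with the smallest p in each direction were taken. The 24 fixed genes and up to 4 members of each list with the smallest p were also named. Some genes that met these rules are not reported here.

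The pipeline was tested on simulated data with the mean levels, depth and dispersion of the real libraries. At a true fold of 8 it recovered 18% of changed genes in neutrophils, 24% in monocytes, 0% for the difference and 40% between cell types. At a true fold of 2 it recovered 0% in each of the 4 comparisons. A list shifted by 1 log2 unit was recovered in all 4, and 0 of 26 unshifted lists were called in any. The simulated genes varied independently, so this does not test correlated lists. The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, limma-trend on log2(TPM + 1), an offset for effective length, fits of a single cell type, a block for the tag, and leaving out each library. After the data were seen, alternatives were added that set both TN1 tag_482 libraries aside, set aside neutrophil library TN2 tag_1341 with monocyte library TN2 tag_706, added a term for low detection, filtered at a mean of 10 CPM, or weighted libraries by quality.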

Results

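The sorted populations carried the programmes of their lineages. Of 13384 genes, 2070 were higher in CCR2+ monocytes and 1663 were higher in neutrophils (edgeR, 5 libraries each), and 2368 of these differed by more than 4-fold. The balance of directions depended on the setting: limma-trend on log2(TPM + 1) gave 4542 and 1215, and edgeR without monocyte library TN2 tag_367 1342 and 1447. All 15 measured neutrophil markers were lower in monocytes, with a median log2 difference of -7.10. Csf3r, the receptor for granulocyte colony-stimulating factor (chromosome 4, 126024550 to 126044440), was at 7900.4 ± 1058 CPM in neutrophils and 164 ± 64.0 CPM in monocytes (log2 difference -5.71 ± 0.33 SE, adjusted p = 2.09e-05). Of 15 monocyte markers, 13 were higher in monocytes, with a median of 3.96. Among them was Ccr2, the chemokine receptor used for the sort (chromosome 9, 124101950 to 124113557, 582 ± 234 against 24.3 ± 30.7 CPM, log2 difference 4.87 ± 0.83, adjusted p = 0.00210).

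Monocytes stood above neutrophils in single genes of antigen presentation and respiration, while with an estimated correlation these lists did not pass (adjusted p = 0.536 for MHC, 0.331 for oxidative phosphorylation and 0.496 for mitochondrially encoded genes). Of 18 MHC genes, 10 were higher and 3 lower in monocytes, with the same counts adjusted over the list alone and a median of 1.85. Cd74, the class II invariant chain, was at 8124 ± 5751 against 216 ± 81.3 CPM, and H2-Ab1, a class II beta chain, at 7199 ± 5983 against 95.3 ± 55.5 CPM, monocytes against neutrophils. Of 25 nuclear-encoded oxidative phosphorylation genes 20 were higher (23 adjusted over the list alone) and 0 lower, with a median of 1.61. All 13 mitochondrially encoded genes were higher, with a median of 2.37 and 2 of them without overlap between the cell types, where neutrophil library TN1 tag_482 was the highest neutrophil library. The other monocyte genes with the smallest p included the matrix protein gene Spon1 (264 ± 35.8 against 15.6 ± 17.7 CPM), the chemokine gene Cxcl16 (251 ± 103 against 17.1 ± 5.70 CPM), the syndecan gene Sdc3 (206 ± 70.0 against 9.51 ± 7.30 CPM), the phosphatase gene Dusp3 (111 ± 6.66 against 15.3 ± 3.44 CPM) and the ribosomal protein gene Rpl13 (632 ± 151 against 87.4 ± 18.6 CPM), at adjusted p from 5.09e-05 to 7.97e-05. Markers of interstitial macrophages (8 of 10 higher, median 4.91, or 4.08 with genes at their bound) and of dendritic cells (6 of 10 higher, median 4.44) were also higher in monocytes. Their lists did not pass camera with an estimated correlation either (adjusted p = 0.125 and 0.496).

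Neutrophils stood above monocytes in single specific granule, migration and type I interferon genes, while with an estimated correlation these lists did not pass (adjusted p = 0.0825, 0.266 and 0.496). Of 18 specific and gelatinase granule genes 14 were lower and 1 higher in monocytes, with a median of -3.52. Lcn2, encoding an iron-withholding granule protein, was at 1716 ± 402 CPM in neutrophils and 28.5 ± 36.0 CPM in monocytes. Medians were -2.61 for myeloid suppressor associated genes (1 higher and 12 lower in monocytes), -1.32 for trafficking and adhesion genes (3 and 12), -0.82 for inflammatory genes (5 and 12), -0.96 for immediate early genes (2 and 9) and -0.24 for glycolysis and hypoxia genes (3 and 7). Of 30 type I interferon-stimulated genes 16 were lower (19 adjusted over the list alone) and 3 higher in monocytes, with a median of -1.59. Isg15, a ubiquitin-like interferon effector, was at 2111 ± 707 CPM in neutrophils and 145 ± 27.1 CPM in monocytes. The neutrophil genes with the smallest p were Trim30b (-4.50 ± 0.23, chromosome 7, 104355382 to 104369884), the fatty acid transporter gene Slc27a4 (-4.83 ± 0.25), the signalling adaptor gene Themis2 (-4.30 ± 0.22), Grina (-4.88 ± 0.27), the interleukin-1 receptor subunit gene Il1rap (-5.24 ± 0.30), the transcription factor gene Ets2 (-3.73 ± 0.22), Csf3r and Ripor2 (-5.16 ± 0.32), at adjusted p from 1.52e-05 for Trim30b to 3.47e-05 for Ripor2.

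By camera 14 of 27 lists passed between the cell types, by fry 15, and with an estimated correlation 0 (smallest adjusted p = 0.0514). Beside each adjusted p the value with an estimated correlation stands in brackets: neutrophil markers 1.34e-15 (0.0825), specific granules 1.93e-09 (0.0825), oxidative phosphorylation 6.35e-08 (0.331), myeloid suppressor 1.68e-07 (0.0514) and type I interferon 2.91e-06 (0.496). Monocyte markers gave 5.09e-06 (0.331), mitochondrially encoded genes 2.17e-05 (0.496), trafficking 5.28e-05 (0.266), immediate early genes 0.000202 (0.493) and interstitial macrophages 0.000403 (0.125). Inflammatory genes gave 0.00158 (0.496), dendritic cells 0.0334 (0.496), glycolysis 0.0366 (0.395) and MHC 0.0366 (0.536). The MHC list missed the threshold without neutrophil library TN2 tag_367 (0.0924), and the glycolysis list without neutrophil library TN1 tag_482 (0.0739) or TN2 tag_1341 (0.0698) or monocyte library TN2 tag_706 (0.0771). Not past the threshold were NADPH oxidase and redox (0.0669), natural killer cells (0.309), cell cycle (0.329) and erythroid cells (0.838). The interferon gamma (0.176), endothelium (0.555), alveolar macrophage (0.745), cytosolic DNA sensing, cytotoxic, azurophil, lymphocyte and epithelium (each 0.883) and stroma (0.966) lists did not pass either, and in these 9 the median, mean and test differed in sign. The eosinophil, basophil and mast cell list and the platelet list had 4 measured members each and were not tested. The median of all genes was 0.46 in this comparison, and 28.5% of genes did not overlap between the cell types against 0.794% by chance.

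In neutrophils, interferon-response lists were higher in TN2 by camera with the preset correlation only, and 0 of their members passed. The interferon gamma response list had 25 of 28 members positive and a median of 1.17, or 0.95 above the median of all genes (0.22), at adjusted p = 0.000244, and adjusted p = 0.806 with an estimated correlation. Without TN2 tag_1341 the excess over all genes was 0.57. Type I interferon-stimulated genes had 29 of 30 positive and a median of 0.88, or 0.66 above all genes, at adjusted p = 2.28e-08, and adjusted p = 0.924 with an estimated correlation. Monocyte markers moved alongside (12 of 15 positive, median 1.29, not passed at adjusted p = 0.344), and their sum was 3657 CPM in TN2 tag_1341 and 1782 to 2066 CPM in the other neutrophil libraries. Irgm2, an interferon-inducible GTPase (chromosome 11, 58199618 to 58222782), was at 53.1 ± 3.02 and 113 ± 16.4 CPM in TN1 and TN2 (2 and 3 libraries), and its relatives Irgm1 at 89.8 ± 36.3 and 241 ± 154 and Ifi47 at 92.2 ± 31.9 and 261 ± 183. Cxcl10, a chemokine induced by interferon (chromosome 5, 92346638 to 92348889), was at 27.5 ± 2.63 and 117 ± 101 CPM, with 233 in TN2 tag_1341. Bst2, a membrane tether of viruses (14.7 ± 9.08 and 54.5 ± 38.2), Mx2, an antiviral GTPase (5.46 ± 2.06 and 25.9 ± 22.8), and the RNA sensor gene Ddx58 (107 ± 18.8 and 208 ± 73.5) were likewise higher in each TN2 than in each TN1 library.

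By fry the adjusted p was 0.331 for the interferon gamma list and 0.964 for the type I list. Of their members 0 passed over all genes and 0 adjusted over the list alone. Without overlap between the tumours were 13 of 28 and 12 of 30 members, all higher in TN2. Chance gives 20% for both directions together, and over all 13384 genes 1577 were higher and 791 lower without overlap. The estimated correlation between members was 0.0709 and 0.471, so these counts are no test of the lists. The MHC list, with 16 of 18 positive and a median of 0.59, did not pass (adjusted p = 0.0684). In it H2-Ab1 was at 41.3 ± 9.35 and 131 ± 35.3 CPM and Cd74 at 131 ± 2.27 and 273 ± 34.8 CPM.

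**Figure D1:**
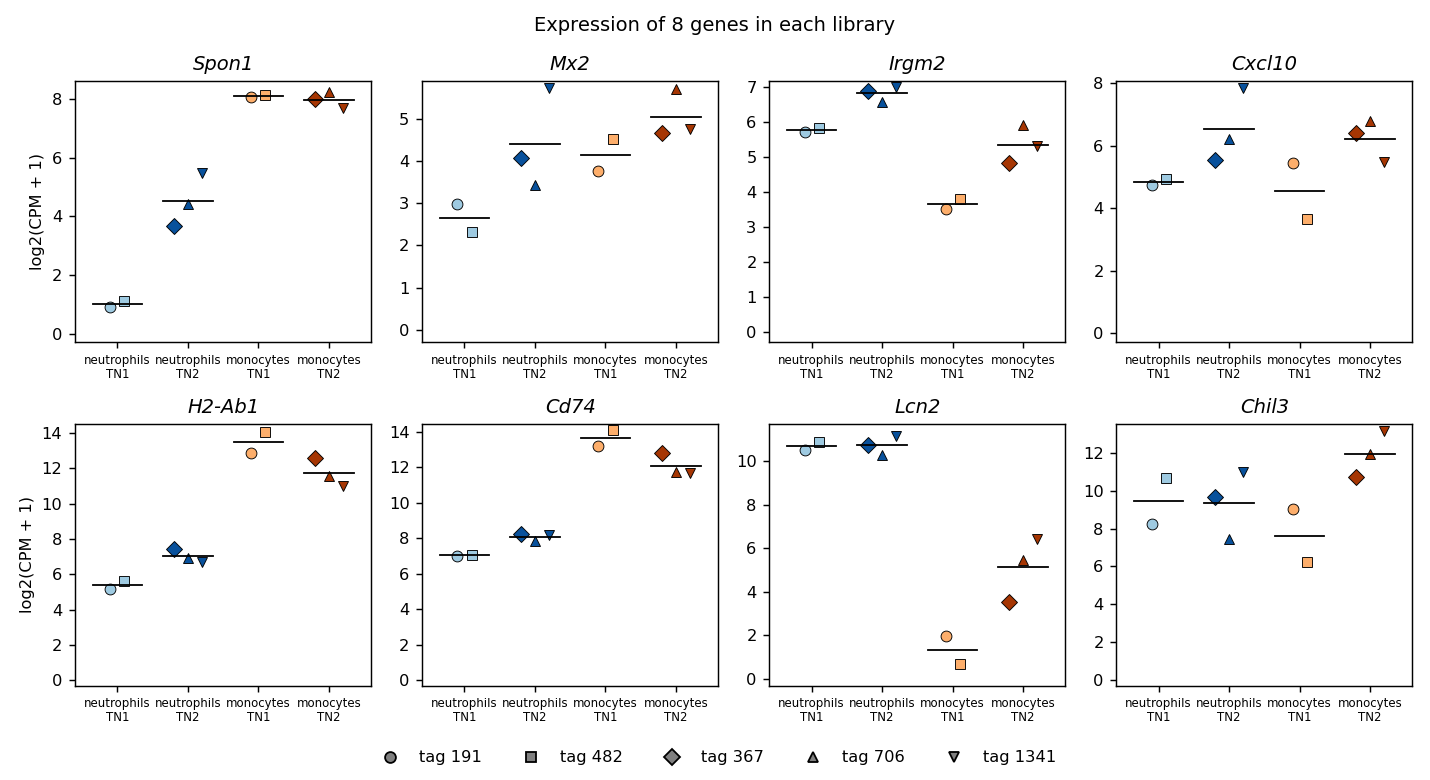
Expression of 8 genes as log2(CPM + 1) on the vertical axis, with 1 symbol per library (shape for the tag), a line for each group mean and the 4 groups side by side. Spon1 lies at 0.896 to 1.14 CPM in TN1 neutrophils and 11.8 to 43.8 CPM in TN2 neutrophils, and Lcn2 at 0.602 to 2.90 CPM in TN1 monocytes and 10.4 to 85.1 CPM in TN2 monocytes.

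Other neutrophil lists moved by less or rested on single libraries. Inflammatory cytokine and NF-kB genes had 23 of 26 members positive and a median of 0.52, or 0.29 above all genes (adjusted p = 0.0117, and adjusted p = 0.924 with an estimated correlation). They included Tnf (37.5 ± 34.8 and 200.2 ± 196 CPM in TN1 and TN2), Ccl2, a monocyte chemoattractant (1.49 ± 1.70 and 12.9 ± 10.1), and Il6 (0.512 ± 0.724 and 4.35 ± 1.65). The adjusted p of this list was 0.803 without TN2 tag_1341 and 0.0719 without TN1 tag_482. Immediate early and heat shock genes had 19 of 24 positive and a median of 0.50, or 0.28 above all genes (adjusted p = 0.0225, and adjusted p = 0.924 with an estimated correlation), for example the phosphatase gene Dusp1 (5607 ± 2265 and 11582 ± 3749 CPM). That list missed the threshold without neutrophil library TN2 tag_1341 (0.344) or TN1 tag_191 (0.236), or without monocyte library TN2 tag_367 (0.0616) or TN2 tag_1341 (0.107).

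Specific and gelatinase granule genes were lower relative to all genes in TN2 neutrophils, with 9 of 18 members negative and a median of -0.07, or -0.29 relative to all genes (adjusted p = 0.00372, and adjusted p = 0.924 with an estimated correlation). The late granule genes Ltf (2823 ± 2217 and 769 ± 1075 CPM in TN1 and TN2), Ngp (5564 ± 3299.5 and 1728 ± 2397) and Camp (832 ± 821 and 242 ± 371) varied between libraries of a tumour by as much as between tumours. Without TN1 tag_482 the adjusted p of this list was 0.154, and without TN2 tag_706 0.0949. All 13 mitochondrially encoded genes were negative, with a median of -1.64 (adjusted p = 0.000989, and adjusted p = 0.924 with an estimated correlation). Library TN1 tag_482 decided this: mt-Cytb was at 3593 CPM there, 172 in TN1 tag_191 and 252 to 606 in TN2. Without TN1 tag_482 the list turned higher in TN2 (adjusted p = 0.00211), and without TN2 tag_706 it did not pass (0.0714).

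Spon1 (chromosome 7, 113765998 to 114043370) was among the neutrophil genes with the smallest p, at 1.02 ± 0.176 and 25.4 ± 16.5 CPM in TN1 and TN2 (log2 difference 4.62 ± 0.62 SE, adjusted p = 0.166). The mitochondrial dehydrogenase gene Acad8 had 0 counts in TN1 and lay at least 4.32 higher on the log2 scale in TN2 (adjusted p = 0.581). Spon1 was abundant in monocytes (264 ± 35.8 CPM). Other monocyte genes were also present in neutrophil library TN2 tag_1341, which held 177 CPM of the coagulation factor gene F13a1 where the other neutrophil libraries held at most 6.31. In the other direction Cep290, Txnl1 (248 ± 29.8 and 112 ± 26.5 CPM) and Gm10718 had the smallest p, each at adjusted p = 0.943. In the authors' deposited table the log2 fold was 1.97 for Spon1, on a scale of log2(TPM + 1).

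Of 13384 genes 0 passed between the tumours in neutrophils by edgeR, and 625 had an unadjusted p under 0.05 where 669 were expected by chance. The DESeq2 Wald test called 87 (78 higher and 9 lower, Spon1 at 4.64e-08), limma-voom 0, limma-trend on log2(TPM + 1) 2, Mrpl2 and BC002163, and edgeR without a filter 2, including Spon1 (0.0145). Among the settings without 1 library, edgeR called genes only without TN1 tag_191. This left the low-detection library TN1 tag_482 alone for TN1 neutrophils, assumed to vary like the other groups. Groups did not overlap for 1577 genes higher and 791 lower in TN2, 17.7% of those tested against 20% by chance. In 11 lists, all outside the 6 past the threshold, the median, mean and test differed in sign.

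Of the fixed genes, the receptor gene Ifngr1 (0.18 ± 0.28), the alarmin genes S100a8 (-0.36 ± 0.80) and S100a9 (0.16 ± 1.24), Csf3r (0.03 ± 0.37), Thbs1, encoding thrombospondin 1 (-0.09 ± 0.72), Il1b (0.36 ± 0.46), Cd274, encoding PD-L1 (-0.43 ± 0.70), Ly6g (0.53 ± 0.87) and the integrin gene Itgam (0.22 ± 0.44) differed between tumours by less than their SE in neutrophils, so no direction was read. The others, Isg15 (0.54 ± 0.34), Irf7 (0.70 ± 0.53), the oxidase gene Cybb (-0.75 ± 0.57), Ccr2 (1.29 ± 1.02), Ly6c2 (2.07 ± 0.97), Tnfsf10, encoding TRAIL (2.83 ± 1.43), and Tmem173, encoding the DNA-sensing adaptor STING (3.06 ± 1.09, 1.02 ± 1.45 and 8.78 ± 3.18 CPM), did not pass either. For Ccr2 and Ly6c2 the rise lay in TN2 tag_1341, with 515 and 1210 counts. The other neutrophil libraries held 26 to 107 counts of Ccr2 and 99 to 162 of Ly6c2. Of the cytosolic DNA sensing list 1 gene, Tlr9, passed adjusted over the list alone and 0 over all genes. Arg1 had 0 counts in all neutrophil libraries, Ifng at most 7, Mpo 21, Nos2 46 and Cxcl9 59.

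In monocytes, the antigen presentation list was lower in TN2 by camera with the preset correlation only, and 0 of its 18 members passed over all genes or over the list alone. Of these MHC genes 15 of 18 were negative, 7 of them without overlap between the tumours, with a median of -0.33, or -0.55 relative to all genes (camera adjusted p = 1.16e-08, and adjusted p = 0.592 with an estimated correlation, and fry 0.577). The split of TN2 tag_706 and TN2 tag_1341 from the other libraries, with these lower, gave a smaller p for this list (3.49e-13 against 8.61e-10). Monocyte markers summed to 4978 CPM in TN2 tag_706 and 9348 to 11631 CPM in the other monocyte libraries. H2-Ab1 was at 6141.5 CPM in TN2 tag_367, 3039 CPM in TN2 tag_706 and 2069 CPM in TN2 tag_1341, so the TN2 libraries differed among themselves. H2-Ab1 (chromosome 17, 34257689 to 34269419) was at 12372 ± 6703 and 3749.9 ± 2127 CPM in TN1 and TN2 (2 and 3 libraries), Cd74 (chromosome 18, 60803848 to 60812652) at 13413 ± 5421 and 4599 ± 2200.2, and the other class II chains H2-Aa at 7979.9 ± 3331 and 2576 ± 1732 and H2-Eb1 at 5859 ± 2341 and 1892 ± 1310.2. Dendritic cell markers were lower alongside, with 8 of 10 negative and a median of -0.97 (adjusted p = 0.00134, and adjusted p = 0.592 with an estimated correlation), such as the lectin gene Cd209a at 307 ± 249 and 65.4 ± 43.0 CPM. Without TN1 tag_482, which held 483 CPM of Cd209a, the adjusted p of the dendritic list was 0.644.

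Mitochondrial transcripts were lower as well. All 13 mitochondrially encoded genes were lower in each TN2 than in each TN1 monocyte library, with a median of -1.79 (adjusted p = 3.86e-12, and adjusted p = 0.592 with an estimated correlation). The complex I gene mt-Nd4 was at 6566 CPM in TN1 tag_482, 1434 in TN1 tag_191 and 863 to 1022 in TN2. TN1 tag_482 set most of the size, since these genes held 19.9% of TPM there, 5.82% in TN1 tag_191 and 4.82% to 5.35% in TN2. Without it the list still passed (adjusted p = 0.00508). Nuclear-encoded oxidative phosphorylation genes lay slightly lower, with 21 of 25 negative and a median of -0.12 (adjusted p = 0.0202, and adjusted p = 0.847 with an estimated correlation). That list missed the threshold without TN1 tag_482 (0.0642) or TN2 tag_706 (0.740), and its members Uqcrq (-0.28 ± 0.31) and Sdhb (-0.26 ± 0.32) turned positive on the log2(TPM + 1) scale.

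Neutrophil marker and granule lists were higher in TN2 monocytes, unevenly between the libraries. Neutrophil markers had 14 of 15 positive, a median of 2.53, or 2.30 above all genes (0.22), and 2 members past the threshold adjusted over the list alone, 0 over all genes (adjusted p = 0.00025, and adjusted p = 0.592 with an estimated correlation). Specific and gelatinase granule genes had 15 of 18 positive, a median of 1.13, or 0.91 with genes at their bound, and 2 adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.592 with an estimated correlation). Lcn2 (chromosome 2, 32384633 to 32388252) was at 1.75 ± 1.63 and 46.3 ± 37.4 CPM in TN1 and TN2, Wfdc21 at 0.866 ± 1.05 and 12.6 ± 8.11, S100a8 at 16.2 ± 10.2 and 213 ± 177, and Chil3, encoding a secreted chitinase-like protein (chromosome 3, 106147554 to 106167564), at 296 ± 315 and 4942 ± 3876. Padi4, the histone-citrullinating enzyme gene (chromosome 4, 140745865 to 140774236), had 0 counts in TN1 and 2.75 ± 1.63 CPM in TN2. The specific granule list missed the threshold without TN1 tag_191 (0.0961) or TN2 tag_1341 (0.159). In TN2 tag_367 the markers S100a9, Cxcr2, Retnlg and G0s2 lay below their TN1 mean. In TN2 tag_706, 20 abundant neutrophil-specific transcripts outside the lists stood at a median of 3.46% of the neutrophil level. That library also held RNA of other lung cells, with 578 CPM of the stromal gene Dcn and 581 CPM of the endothelial gene Cldn5, where the other monocyte libraries held at most 0.729 and 36.1. Alveolar macrophage markers summed to 528 CPM there and 41.8 to 70.8 CPM in the others (7 of 8 positive, median 2.56, not passed at adjusted p = 0.424).

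**Figure D2:**
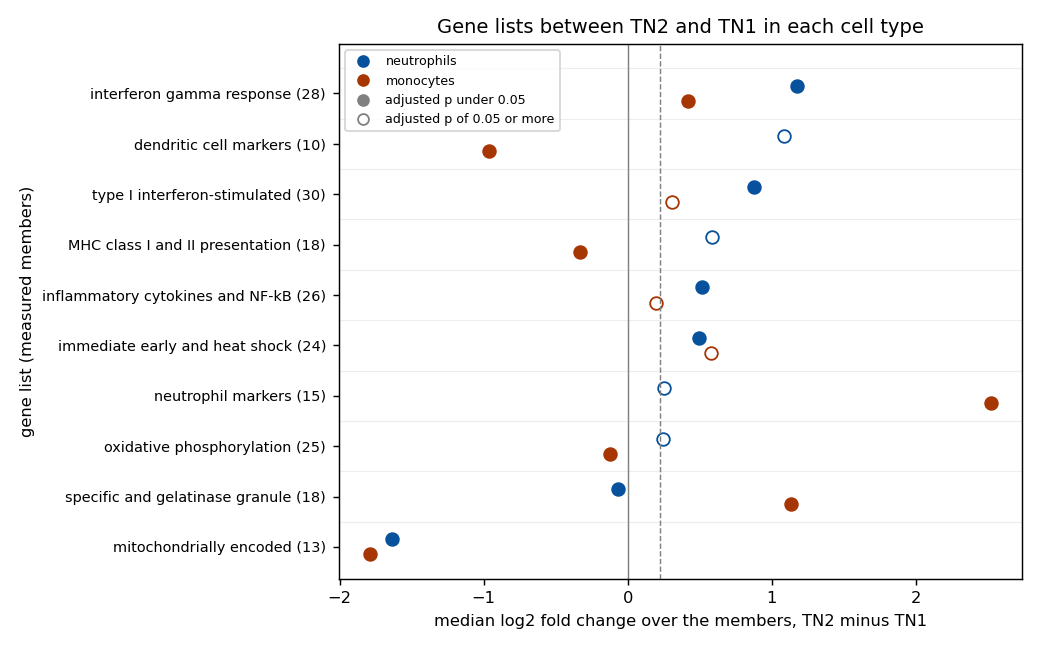
Median log2 fold change (TN2 minus TN1, horizontal axis) of 10 gene lists with their number of measured members, neutrophils in blue and monocytes in brown, filled where camera with a preset correlation gave an adjusted p under 0.05. The dashed line is the median of all genes, 0.22, and neutrophil markers reach 2.53 in monocytes against 0.25 in neutrophils.

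The interferon gamma response list was higher in TN2 monocytes, with 22 of 28 members positive, a median of 0.42, or 0.20 above all genes, and 3 members past the threshold adjusted over the list alone, 0 over all genes (camera adjusted p = 0.0302, and adjusted p = 0.614 with an estimated correlation). Irgm2 was at 11.6 ± 1.81 and 41.8 ± 16.3 CPM in TN1 and TN2, its relatives Igtp at 27.0 ± 15.2 and 84.8 ± 18.1 and Tgtp1 at 0.120 ± 0.170 and 13.3 ± 18.5, and the transcription factor gene Irf1 at 93.4 ± 35.7 and 351 ± 275. The list missed the threshold without TN1 tag_191 (0.234), TN2 tag_367 (0.213) or TN2 tag_1341 (0.0517). Type I interferon-stimulated genes, with 21 of 30 positive and a median of 0.31, did not pass (adjusted p = 0.296).

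By edgeR 0 of 13384 genes passed between the tumours in monocytes, with 379 at an unadjusted p under 0.05 where 669 were expected by chance and a smallest adjusted p of 1. Padi4, Lcn2 and Wfdc21 had the smallest p among the higher genes, and the receptor gene Klra17 (78.3 ± 13.3 and 28.9 ± 8.50 CPM in TN1 and TN2), Gm10443 and Cd74 among the lower. The DESeq2 Wald test called 22 (17 higher and 5 lower), with Lcn2 at adjusted p = 0.00029, Wfdc21 at 0.00353, S100a8 at 0.0183 and Irgm2 at 0.0356. Limma-voom called 0, limma-trend 0 and limma-voom with quality weights 2, Gm10443 and Rpl38-ps2. The genes that passed in the authors' deposited table were the pseudogene Rpl38-ps2 (log2 fold -12.44) and Gm13577 (-9.09). Without TN1 tag_191 edgeR called genes, but this left the low-detection library TN1 tag_482 alone for TN1 monocytes. Groups did not overlap for 1653 genes higher and 1035 lower in TN2, 20.1% of those tested against 20% by chance. In 9 lists, all outside the 7 past the threshold, the median, mean and test differed in sign.

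Of the fixed genes, Ccr2 (-0.47 ± 0.95), Ly6c2 (0.07 ± 0.89), Ifngr1 (0.14 ± 0.28), Irf7 (0.13 ± 0.52), Tmem173 (0.38 ± 0.92), Tnf (-0.40 ± 0.81), Il1b (0.12 ± 0.46), Thbs1 (0.55 ± 0.73), Cybb (0.05 ± 0.58) and Cd274 (0.07 ± 0.71) differed between tumours by less than their SE in monocytes, so no direction was read. Isg15 (0.38 ± 0.34), Cxcl10 (1.55 ± 0.78), Tnfsf10 (2.40 ± 1.40), S100a9 (3.54 ± 1.45), Ly6g (2.53 ± 1.12), Itgam (0.64 ± 0.45) and Csf3r (0.75 ± 0.38) were not past the threshold either. A monocyte library held at most 37 counts of Ifng, 15 of Arg1, 18 of Nos2, 6 of Mpo and 149 of Cxcl9.

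The tumour effect on the antigen presentation list differed between the cell types by camera with the preset correlation only. All 18 MHC genes had a lower TN2 minus TN1 difference in monocytes than in neutrophils, with a median of -0.64 and 4 members past the threshold adjusted over the list alone, 0 over all genes (camera adjusted p = 7.57e-06, and adjusted p = 0.665 with an estimated correlation, and fry 0.938). H2-Ab1 differed by -3.39 ± 0.74, from -1.72 ± 0.50 in monocytes and 1.67 ± 0.54 in neutrophils, and Cd74 by -2.60 ± 0.59, from -1.54 ± 0.41 and 1.06 ± 0.43. Monocyte markers (14 of 15 negative, median -1.76, adjusted p = 0.0747) and dendritic cell markers (7 of 10 negative, median -1.40, adjusted p = 0.358) moved the same way without passing. The excess of H2-Ab1 in TN2 neutrophil libraries was 4.25%, 2.64% and 2.00% of its TN2 monocyte level in tag_367, tag_706 and tag_1341. There 20 abundant monocyte-specific transcripts, H2-Ab1 among them, had medians of 1.67%, 1.82% and 18.8%. Neutrophil markers (14 of 15 positive, median 2.00, adjusted p = 0.000425, and adjusted p = 0.965 with an estimated correlation) and specific granule genes (16 of 18 positive, median 1.48, 2 adjusted over the list alone, adjusted p = 0.000607, and adjusted p = 0.665 with an estimated correlation) differed the other way. For interferon genes a difference between the cell types was not shown: the type I list had a median of -0.53 (adjusted p = 0.0856) and the interferon gamma list -0.43 (adjusted p = 0.685).

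By edgeR 0 genes passed for this difference, with 472 at an unadjusted p under 0.05. The DESeq2 Wald test called 21 (4 higher and 17 lower), limma-voom 0 and edgeR without a filter 1. Spon1 (-4.73 ± 0.75, adjusted p = 0.625) and Utp15 were among the negative genes with the smallest p, and Padi4, 4930438A08Rik and Lcn2 (4.64 ± 1.15) had the smallest p among the positive. Without neutrophil or monocyte library TN1 tag_191 edgeR called genes, but this left the low-detection library TN1 tag_482 alone for TN1 in that cell type. In simulated data this comparison recovered 0% of genes changed 16-fold, so the count of 0 sets no bound. In 4 lists, all outside the 3 past the threshold, the median, mean and test differed in sign.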

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

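The tests of RNA carried over between the sorted populations were chosen after the results, and the shares they use, had been seen, and the differences between the cell types were planned. These 3 lists stood out because the tumour effect differed between monocytes and neutrophils in a test of the difference itself. The list of MHC class I and II presentation had an adjusted p of 7.57e-06, with 18 of 18 members negative and a median of -0.64. Specific and gelatinase granule genes had 0.000607, with 16 of 18 positive and a median of 1.48, and neutrophil markers 0.000425, with 14 of 15 positive and a median of 2.00. With an estimated correlation these were 0.665, 0.665 and 0.965, so each difference rests on the preset correlation. Monocyte markers also had a lower tumour effect in monocytes than in neutrophils (14 of 15 negative, median -1.76, adjusted p = 0.0747). Monocyte RNA in the TN2 neutrophil libraries would act in the same direction on the MHC list and stays open, as untested for it. The excess of H2-Ab1 in tag_1341 was 2.00% of the monocyte level, where 20 abundant monocyte-specific transcripts had a median of 18.8%. In tag_367 and tag_706 the excess was 4.25% and 2.64%, above the medians of 1.67% and 1.82% there. The libraries thus gave no common answer, and H2-Ab1 is itself 1 of the 20 transcripts.

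Neutrophil marker and granule lists were higher in TN2 monocytes with the preset correlation only (with an estimated correlation adjusted p = 0.592 and 0.592), and neutrophil RNA in these libraries is a candidate explanation. Whole neutrophils would bring all their abundant transcripts, so 20 abundant neutrophil-specific transcripts outside the lists were set against all listed genes, as shares of the neutrophil level above TN1 monocytes. The listed genes were split by whether TN1 monocytes held more than 1% of the neutrophil level. For the 15 that did, such as the genes Cd177 and Chil3, 20 of 20 lay below 0.5 of the listed genes' median share in TN2 tag_367 (median 0.0615% against 5.52% for the listed genes) and 19 in TN2 tag_1341 (median 0.340% against 11.2% for the listed genes). This argues against RNA like that of the sorted neutrophils as the whole cause of the median rise of those genes in those libraries. Not each of them rose: Il1r2 (-1.21%), Adam8 (-4.08%) and Mmp25 (-2.06%) were lower in TN2 tag_367, and Mmp25 (-8.31%) in TN2 tag_1341. In TN2 tag_706, 0 of 20 abundant transcripts lay below, where the lower quartile of the listed genes was -2.59%, so there was no common rise to explain. For the 15 neutrophil-specific listed genes, 0 of 20 lay below in TN2 tag_706 (median 3.46% against 2.43% for the listed genes), as neutrophil RNA predicts. In TN2 tag_1341 8 did (median 0.340% against 0.180% for the listed genes), between the limits of 5 and 15, so neutrophil RNA and a change within monocytes cannot be told apart there. In TN2 tag_367 7 did, and these listed genes had no common rise to explain (median 0.00553%, lower quartile -0.0269%). RNA of neutrophils with another profile, a change within the monocytes and the tumour itself stay open, as untested.

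Spon1 was higher in TN2 neutrophil libraries without passing the threshold. Monocyte RNA is a candidate explanation, tested on 20 transcripts abundant in the monocyte source and at most 2% of that level in TN1 neutrophils. In the TN2 neutrophil library tag_1341, 3 of 20 lay below 0.5 of the share that Spon1 needs (18.8% where 16.8% was needed), as monocyte RNA predicts. The most abundant of the 20, H2-Ab1, was among these 3 at 2.00%, so RNA like that of the sorted TN2 monocytes did not match in that transcript. In tag_367 the number was 11 with the median of the TN2 monocyte libraries as source and 14 with the monocyte library of the same tag. In tag_706 it was 19 with the median as source (1.82% where 7.65% was needed) and 6 with the library of the same tag. The latter 20 transcripts included the stromal gene Dcn and the keratin genes Krt4 and Krt13, so the 6 does not test monocyte RNA alone. In tag_367 and tag_706 monocyte RNA and a change within neutrophils cannot be told apart. Both numbers in tag_367 lie between the limits of 5 and 15. For tag_706, whose monocyte library held stromal RNA, the source of the same tag gives no usable answer, and the limits asked for the same answer from both sources.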

How the results depend on the processing

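The alternatives that set libraries aside together, the low-detection term, the filter at 10 CPM and the quality weights were chosen after the data had been seen, and the others were planned. For the count of changed genes, DESeq2's Wald test gave 87 in neutrophils, 22 in monocytes and 21 for the difference where edgeR gave 0. Without a filter on low counts these were 2, 0 and 1, with limma-trend on log2(TPM + 1) 2, 0 and 0, and with quality weights in limma-voom 0, 2 and 0. Between the cell types limma-trend gave 5757 genes where edgeR gave 3733. The cause was not tested. DESeq2 size factors, limma-voom, the length offset and the filter at 10 CPM gave 0 in the tumour comparisons and their difference, and 3761, 4742, 3686 and 3279 between the cell types. Leaving out 1 library gave 0 to 508 genes in neutrophils, 0 to 129 in monocytes, 0 to 374 for the difference and 2687 to 3854 between the cell types. The highest tumour counts arose where the low-detection library TN1 tag_482 was left as the lone TN1 library of a cell type.

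For the lists past the threshold, 6 in neutrophils, 7 in monocytes, 3 for the difference and 14 between the cell types, an estimated inter-gene correlation gave 0, 0, 0 and 0, and fry 0, 0, 0 and 15. Leaving both libraries of tag_482 aside gave 11 in monocytes and 8 for the difference, leaving TN2 neutrophils tag_1341 and TN2 monocytes tag_706 aside 13 and 5, and the low-detection term 6 for the difference. Leaving out 1 library gave 4 to 11 lists in neutrophils, 7 to 12 in monocytes, 3 to 8 for the difference and 13 to 15 between the cell types. The mitochondrially encoded list in neutrophils was reversed with both libraries of tag_482 aside (5.37e-08) and without TN1 tag_482 (0.00211), over a range of 1.23e-15 to 0.0714 without 1 library, where the share of mitochondrial RNA in that library shows the cause. With the preset correlation, the interferon gamma list in neutrophils passed in 10 of 10 settings without 1 library. So did the MHC list in monocytes and for the difference. Within a cell type, settings without a library of the other cell type left the compared libraries unchanged. Settings with a lone TN1 library took its spread from the other groups. With an estimated correlation these lists did not pass (camera adjusted p = 0.806, 0.592 and 0.665), so the settings do not show that they hold.

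With the tag as a random replicate block, limma-voom gave 0, 0, 0 and 5302 genes and 6, 7, 3 and 15 lists in the same order, and with a fixed block edgeR gave 0 genes for the difference and 3335 between the cell types. Each tag occurs in both cell types, but the labels do not say that a tag is an animal, and the block correlation was 0.151. The deviations of the libraries of a tag from their group means correlated at 0.380 for tag_706, 0.342 for tag_1341, 0.0890 for tag_191 and tag_482, whose deviations mirror each other and give a single value, and -0.0569 for tag_367. The libraries of tag_367 did not correlate best with their own tag, so the data do not pair all tags. The median of all genes moved from 0.22 in both cell types to 0.08 in neutrophils and 0.40 in monocytes on the log2(TPM + 1) scale. Depth limits the genes with 0 counts in a group, for which only a bound was given.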

Other observations

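Some genes known as markers of other cells differed between the populations, while their lists did not pass between the cell types (adjusted p = 0.745 for alveolar macrophages and 0.883 for lymphocytes). Siglecf, a lectin gene of eosinophils and alveolar macrophages (chromosome 7, 43351341 to 43359531), was higher in neutrophils than in monocytes (53.7 ± 14.2 against 6.70 ± 8.07 CPM, log2 difference -3.31 ± 0.72 SE, adjusted p = 0.00768). Cd3d, a T cell receptor subunit gene (chromosome 9, 44981786 to 44987339), was also higher in neutrophils (32.4 ± 8.24 against 3.73 ± 3.28 CPM, -3.07 ± 0.66, adjusted p = 0.00731), in a strain that lacks T cells. Klrk1, an activating receptor gene of natural killer cells, was at 63.1 ± 53.9 CPM in monocytes and 2.01 ± 2.13 CPM in neutrophils (adjusted p = 0.00641). The summed stromal markers were at 3770.0 CPM in monocyte library TN2 tag_706 and 1.27 to 322 CPM in the other monocyte libraries, and endothelial markers at 2393 and 23.6 to 255 CPM.

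The tests below without single libraries and of the monocyte share were chosen after the result had been seen, and the counts of other splits for that list and between the cell types were planned, while those for the number of lists and the MHC list within a cell type were added. The interferon gamma response list was higher in TN2 neutrophils by camera with the preset correlation only, and 0 of its 28 members passed. For this list 2 technical explanations were tested. Without the TN2 neutrophil library tag_1341 the list had a median of 0.77 against 0.21 for all genes and 22 of 28 members positive. Its excess was thus not confined to that library. The camera adjusted p with the preset correlation was 0.0112 there. That value cannot decide on monocyte RNA, since splits that mix the tumours also gave small unadjusted p. An example is 0.00686 for TN1 tag_482 with TN2 tag_706 against the rest. Monocyte RNA in all 3 TN2 neutrophil libraries is argued against as the whole cause. At the upper quartile share of abundant monocyte-specific transcripts, RNA like that of the sorted TN2 monocytes raises the median of the list by at most 0.0849, where the observed excess over all genes was 0.51 to 0.99. The low-detection TN1 neutrophil library tag_482 stays open. Without it the list had an adjusted p of 0.000783, a median of 0.78 against 0.15 and 25 of 29 positive, but this leaves a lone TN1 neutrophil library, with the spread supplied by the other groups. Of the 10 splits of the 5 neutrophil libraries into 3 and 2, 2 gave as small a p, 1.81e-05 for the real split and 7.08e-07 for the smallest other. That split sets TN2 tag_367 and TN2 tag_1341, the higher side, against TN2 tag_706 and both TN1 libraries, so it shares part of the tumour contrast, and 10 splits are too few for a share under 0.05. Correlation between the genes stays open too, since the list did not pass with an estimated correlation (0.806).

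Over the same 10 splits as many lists as in the real one were past the threshold in 6 splits of the neutrophil libraries (real 6, highest other 13) and in 10 splits of the monocyte libraries (real 7, highest other 18). For the MHC list in monocytes the p was 8.61e-10 for the real split and 3.49e-13 for the smallest other, TN2 tag_706 and TN2 tag_1341 lower than the rest. The number of lists therefore does not set the tumours apart from other groupings, the reason was not tested, and 10 splits are too few for a share under 0.05. Between monocytes and neutrophils 1 of 100 splits, the real one, gave as many genes (3867 in a fit of these 2 groups, highest other 0). For the lists 26 of 100 splits gave as many (real 13, highest other 18). Each other split holds both cell types on each side, which puts their difference into the residual, so neither count measures chance and the limits set beforehand do not apply.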
